A study of Mus musculus with 6 samples.

How the data were processed

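RNA sequencing libraries came from 6 samples of cultured mouse spermatogonial stem cells, 3 untreated and 3 treated with 100 µM bisphenol A (BPA) for about 4 days. Total RNA was extracted with miRNeasy columns and made into libraries with the TruSeq RNA kit v2, per the labels' protocols. That kit does not mark strand. TopHat2 2.0.9, HTSeq and the mm10 genome build are named in the submitters' processing notes. The HTSeq version, read length, strand setting and annotation release are not given in the sources used here.

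The deposited table holds 34745 Ensembl genes with raw gene counts and FPKM values made by the authors, 1 column of each per sample, together with gene names, loci and KEGG terms. The deposited FPKM values equal the counts divided by a gene length and by the column's summed counts, to within a relative deviation of 9.2e-04, so they were used only to recover the gene lengths. The deposited counts are whole numbers that are not normalised, and all tests used them. Of the gene identifiers 98.6% were found in GENCODE vM21, and 80.8% of those had an identical locus there. GC content was taken from the longest transcript in that annotation and was available for 99.9% of the tested genes. Coordinates are those of the deposited table (mm10).

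Each column was matched to its sample by the code in the sample's title. Library totals were 13453280 to 22286517 counts, with 13638 to 16013 genes counted per library. Mitochondrial genes took 1.97% to 2.69% of the counts and the 10 most abundant genes 6.1% to 6.9%. The replicate pairs differed by more than sampling noise: the chi-square per degree of freedom was 19.2 to 95.1, highest for the pairs with BPA replicate 2 (69.9 and 95.1). The biological coefficient of variation was 0.44 over all tested genes, with a median from 1.05 below 1 CPM to 0.16 above 256 CPM, so small changes of rare transcripts were not detectable. Intervals and floors given for single genes cover counting error only.

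The counts were filtered with filterByExpr, scaled by the trimmed mean of M-values and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), BPA against untreated with no block, with Benjamini-Hochberg adjustment and a threshold of 0.05. "edgeR adjusted p" stands for this test. The standard error of a log2 fold change is its size over the square root of F. The 33 gene lists (780 entries) were tested with camera of limma 3.58.1 on log CPM with a preset correlation of 0.01, and with an estimated correlation and fry beside it, adjusted over the lists. Lists, tests, alternatives and the rule for named genes were fixed before the data were examined.

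The rule took the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold whose groups did not overlap and whose mean was at least 1 CPM. It left out predicted gene models and pseudogenes, of which 51 passed the threshold. From each list it took up to 4 members past the threshold with the smallest adjusted p, or the 2 most abundant where none passed. A set of stem cell, hormone receptor and methylation genes was always named. The rule gave 133 genes, 111 of them past the threshold, and 47 of those passed it without each library in turn. The text gives values for a part of the 133 and prefers those 47. Of the genes always named, Gper1, Esrrg and Cyp1b1 had too few counts to be tested. Where a group had 0 counts, the fold was computed against a floor of 3 counts over the group.

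The alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors in edgeR, upper quartile or library size scaling, no low-count filter, at least 1 CPM in 3 samples, an FDR of 0.01, a replicate block and leaving out each library in turn. A correction of each library for GC content and gene length by lowess (span 0.3) was added after the results were seen. Ranges of the camera adjusted p over the alternatives hold the preset correlation, and leave out the estimated correlation and fry. The tests were run on simulated counts for 12799 genes with the means and library sizes of these samples and 200 changed genes. There edgeR recovered 37% of 2-fold and 71% of 4-fold changes, with 7 of 115 calls false, and DESeq2 recovered 47% and 75%, with 29 of 151 false. On 12831 simulated genes camera called 5 of 5 shifted lists and 0 of 30 unchanged ones with the preset correlation, and 4 of 5 and 0 of 30 with an estimated one. The simulated genes were drawn independently. These runs therefore do not show how often the preset makes false calls for correlated lists, such as the immediate early list (estimated correlation 0.462). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.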

Results

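RNA sequencing measured gene expression in cultured mouse spermatogonial stem cells, the germ cells that sustain sperm production, with and without bisphenol A (BPA), a plastics monomer known as an endocrine disruptor. The cultures came from DBA/2J and C57BL/6J hybrid mice of postnatal day 6 and were at passages 15 to 20. There were 3 untreated libraries and 3 libraries from cultures given 100 µM BPA for about 4 days. Summed gene counts were 19183912, 13453280 and 13888739 in untreated replicates 1 to 3, and 14232872, 21444077 and 22286517 in BPA replicates 1 to 3. The labels do not say that the replicates were separate cultures or animals, so the p-values measure only the spread between these samples and do not show whether it is biological. All values below are normalised counts scaled to library size (CPM) as mean ± SD with n = 3 per group, and log2 fold changes are BPA over untreated with their standard error (SE).

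The comparison asked how the transcriptome of the BPA cultures differed from that of the untreated ones. The controls are titled untreated, and their titles name no vehicle. If none was given, effects of a solvent or of handling cannot be told apart from those of BPA. Of genes of the endoplasmic reticulum stress and integrated stress response, 18 of 34 were higher under BPA. Of antioxidant, mitotic, cholesterol synthesis and nuclear respiratory chain genes, 14 of 29, 11 of 25, 9 of 25 and 12 of 38 were lower. All of these lists passed the camera test with a preset correlation but not with an estimated one (camera adjusted p = 0.163, 0.163, 0.163, 0.163 and 0.409). Within the stress list, 15 of 16 targets of the transcription factor ATF4 rose, but only 1 of 13 chaperone, folding and degradation genes. These 2 sets were drawn up after the values were seen. Among stem cell factors, Nanos3 and Pou5f1 fell, and Stra8, a gene induced by retinoic acid at the onset of spermatogonial differentiation and meiosis, rose. The lists of stem cell maintenance and differentiation did not pass as groups (camera adjusted p = 0.504 and 0.935). Of 28 stem cell genes 2 were higher and 5 lower, and of 17 differentiation genes 2 were higher and 3 lower. Of 13287 genes tested, 1415 passed a false discovery rate (FDR) of 0.05, with 580 higher and 835 lower under BPA. A change of at least 2-fold was seen for 745 of them, 367 higher and 378 lower. Scaling by library size alone gave 831 higher and 786 lower genes, and moved the median log2 fold change of all tested genes from 0.10 to 0.21. The values of the groups did not overlap for 31.3% of the tested genes, where chance gives 10%.

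**Figure D1:**
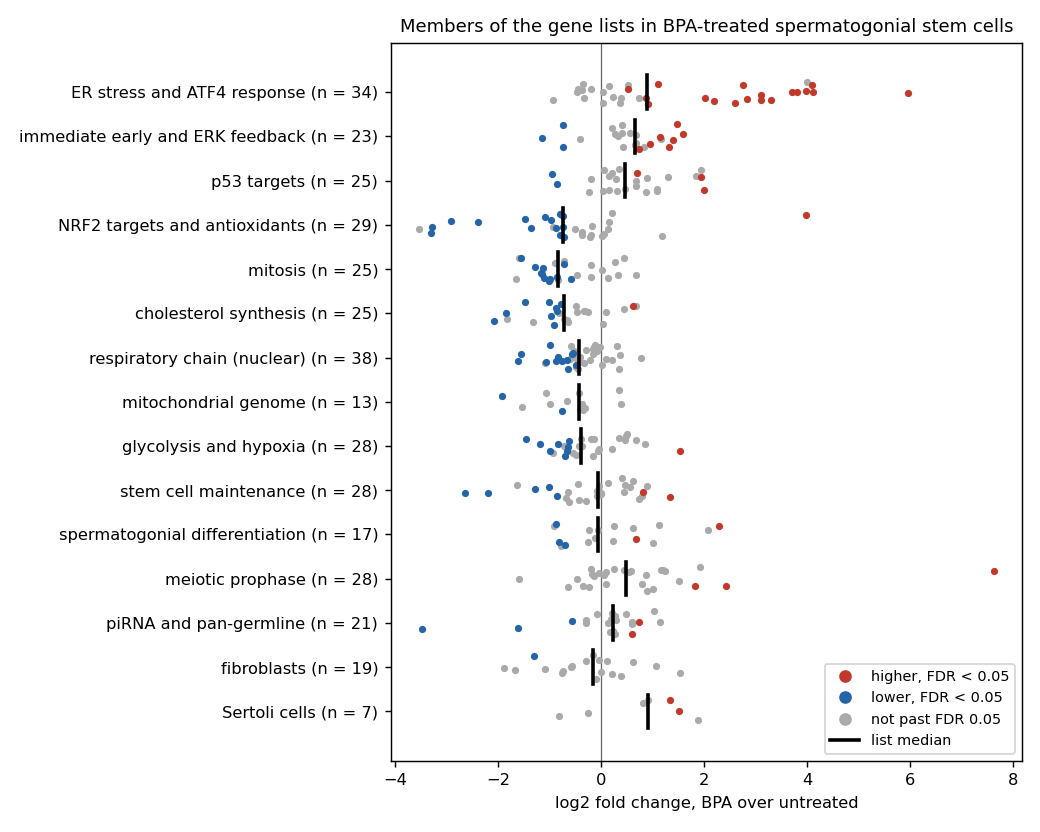
Log2 fold change of each tested member (points) of 15 gene lists, with the list median as a black bar. Red and blue points passed FDR 0.05 as higher or lower under BPA. The median of the list for endoplasmic reticulum stress and ATF4 was 0.89, and those of the NRF2, mitosis and cholesterol lists were -0.73, -0.84 and -0.72.

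Of 34 tested genes of the endoplasmic reticulum stress and integrated stress response, 18 were higher and 0 lower in edgeR (19 and 2 when adjusted over the list alone), with a median log2 fold change of 0.89. The number lower was 3 without BPA replicate 2 and 4 after the GC and length correction. Atf4, the transcription factor at the centre of the response (ENSMUSG00000042406, chromosome 15, 80255184 to 80257540, mm10), rose from 55.7 ± 8.39 to 782 ± 29.7 CPM (log2 fold change 3.81, SE 0.17, edgeR adjusted p = 1.2e-07). Trib3, a pseudokinase induced by ATF4 (chromosome 2, 152337422 to 152344032), rose from 59.6 ± 1.73 to 1032 ± 202 CPM (4.11, SE 0.18, edgeR adjusted p = 1.2e-07). The asparagine synthetase gene Asns rose by 2.75 (SE 0.14), and Herpud1, a component of endoplasmic reticulum degradation, by 3.70 (SE 0.19). Chac1, which encodes a glutathione-degrading enzyme, went from 9.79 ± 4.65 to 609 ± 138 CPM. Ddit3, which encodes the stress factor CHOP and was chosen after its values were seen, rose by 3.10 (SE 0.42). These genes passed the threshold without each library in turn. The camera test of the list gave an adjusted p of 3.9e-07 with a preset correlation, and the camera adjusted p = 0.163 with an estimated correlation. Of 13 chaperone, folding and degradation genes in the list, a set that left out Herpud1, 1 rose. The chaperone gene Hspa5, chosen after its values were seen, was at -0.47 (SE 0.26, edgeR adjusted p = 0.29). The KEGG term for protein processing in the endoplasmic reticulum had 10 of 154 genes higher and 10 lower (camera adjusted p = 0.949 over 269 terms).

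**Figure D2:**
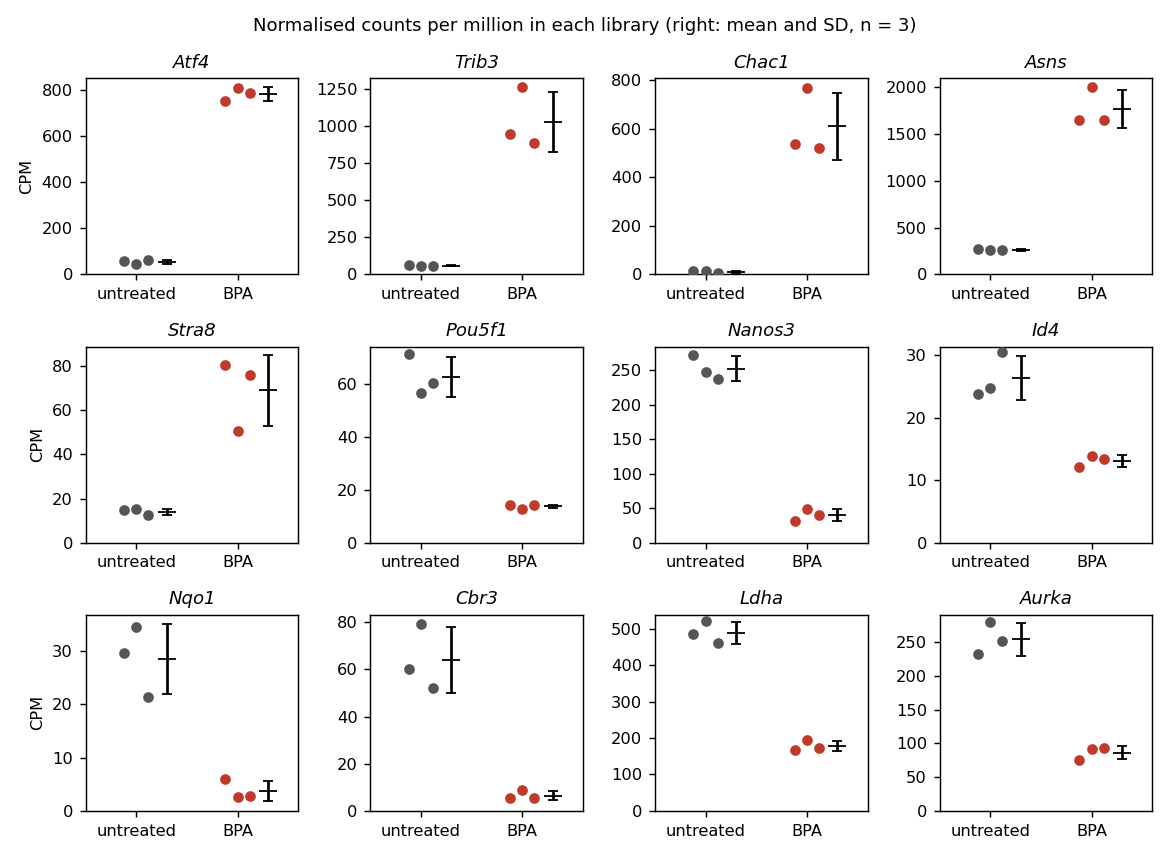
Normalised CPM of 12 genes in each of the 6 libraries (points), with the group mean and SD (bars, n = 3) beside them on linear axes that start at 0. Atf4, Trib3, Chac1, Asns and Stra8 lay higher in all 3 BPA libraries, and the other genes lay lower.

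Stem cell maintenance genes did not move as a group: of 28 tested, 2 were higher and 5 lower (3 and 5 when adjusted over the list alone), 4 and 4 with scaling by library size, and the camera adjusted p was 0.504. Nanos3, an RNA-binding factor of germ cells (ENSMUSG00000056155, chromosome 8, 84173733 to 84176552), fell from 252 ± 17.9 to 40.2 ± 8.52 CPM (-2.65, SE 0.19, edgeR adjusted p = 8.5e-06). Pou5f1, which encodes OCT4, fell from 62.5 ± 7.62 to 13.7 ± 0.694 CPM (-2.19, SE 0.23). Egr3 fell by 1.28 on the log2 scale and Bcl6b by 0.85, and Id4 fell from 26.4 ± 3.59 to 13.1 ± 0.978 CPM, while Egr2 rose by 1.34 and Sall4, chosen after its values were seen, by 0.82. Egr3 and Bcl6b missed the threshold without untreated replicate 1, untreated replicate 3 or BPA replicate 1, Egr3 also without BPA replicate 3 and Bcl6b also without untreated replicate 2 (highest edgeR adjusted p = 0.084 and 0.0934). Id4 missed it without any library other than BPA replicate 2 (up to 0.151 in edgeR), Egr2 without untreated replicate 1 or 2 or BPA replicate 3 (up to 0.0842), and Sall4 without any untreated replicate or BPA replicate 1 (up to 0.163). Components of the GDNF receptor did not pass the test: Gfra1 was at 54.9 ± 17.9 and 75.4 ± 15.2 CPM and Ret at 391 ± 10.8 and 432 ± 148 CPM in untreated and BPA cultures. Zbtb16, the classical marker PLZF, was at 41.7 ± 10.6 and 40.8 ± 5.88 CPM, and Etv5 at 325 ± 14.6 and 443 ± 128 CPM (edgeR adjusted p = 0.96 and 0.16). Etv5 passed with scaling by library size (edgeR adjusted p = 0.0368) and after the GC and length correction (0.0284). Nanos2 was at 13.3 ± 5.65 and 4.33 ± 3.7 CPM (edgeR adjusted p = 0.12), and 49.0% of its exon length overlaps another annotated gene. Nanos2 passed as lower without BPA replicate 1 (edgeR adjusted p = 0.0445), with no low-count filter (0.0303), with a replicate block (0.0365), in DESeq2 (adjusted p = 0.0485) and in limma-voom (0.0472).

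Differentiation genes went both ways. Of 17 tested, 2 were higher and 3 lower (3 and 5 when adjusted over the list alone; camera adjusted p = 0.935). Scaling by library size gave 4 higher and 4 lower, and the GC and length correction 5 higher and 3 lower (median -0.06 before and 0.21 after). Stra8 (ENSMUSG00000029848, chromosome 6, 34920163 to 34939344) rose from 14.0 ± 1.43 to 68.9 ± 16.2 CPM (2.29, SE 0.26, edgeR adjusted p = 0.00023), and Uchl1 fell by 0.82 on the log2 scale (SE 0.15). Sohlh1, a transcription factor of differentiating spermatogonia, rose by 0.68 and lost the threshold without untreated replicate 1 or 2 or BPA replicate 1 (edgeR adjusted p up to 0.0766). Crabp1 and Upp1, the latter chosen after its values were seen, fell by 0.69 and 0.87. Both lost the threshold without untreated replicate 1 or 2 or BPA replicate 1 or 3 (edgeR adjusted p up to 0.133 and 0.16), and Crabp1 was at -0.08 after a correction for GC content and gene length. Kit was at 17.5 ± 6.75 and 14.8 ± 4.2 CPM (edgeR adjusted p = 0.74). Among 28 meiotic genes 3 were higher and 0 lower, the same counts when adjusted over the list alone (median 0.49, with Prdm9 at its bound too; camera adjusted p = 0.412, 0.0195 without BPA replicate 2, range over the alternatives 0.0195 to 0.834). The number higher was 6 without BPA replicate 2, 0 without any other single library or in limma-voom, and 1 with a replicate block. Prdm9, which places meiotic recombination sites, had 0 counts in untreated and 79 in BPA libraries and was at least 19.7-fold higher against a floor of 3 counts over the group. Tex11 and Mei4 rose by 2.43 and 1.82. Prdm9 lost the threshold without any single library (edgeR adjusted p up to 0.193), and Tex11 and Mei4 without any library other than BPA replicate 2 (up to 0.113 and 0.253). In the list of piRNA and other germline genes 2 of 21 were higher and 3 lower, again the same over the list alone (camera adjusted p = 0.887). Dppa3 fell by 3.48 on the log2 scale and lost the threshold without untreated replicate 2 (edgeR adjusted p = 0.0949). The higher ones were Mov10l1 (0.74) and Piwil2 (0.59), which lost the threshold without untreated replicate 1 or 2 or BPA replicate 3, and Piwil2 also without BPA replicate 1 (edgeR adjusted p up to 0.116 and 0.128). The other lower ones were Dnmt3l (-1.61; lost without untreated replicate 1 or 2 or BPA replicate 3, edgeR adjusted p up to 0.0611) and Dnd1 (-0.57, chosen after its values were seen; lost without any library other than BPA replicate 2, up to 0.144). Without BPA replicate 2 the number higher was 7, and with no low-count filter 4 were higher and 3 lower. Ddx4 was at 29.1 ± 2 and 33.0 ± 20.6 CPM and Dazl at 185 ± 9.28 and 218 ± 96.7 CPM, and neither passed the test, although Dazl passed as higher without BPA replicate 2 (edgeR adjusted p = 0.0104).

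Of 29 antioxidant genes, many of them targets of the transcription factor NRF2, 14 were lower and 1 higher (18 and 1 when adjusted over the list alone; median -0.73, camera adjusted p = 8.4e-07, and adjusted p = 0.163 with an estimated correlation). Cbr3, a carbonyl reductase, fell from 63.9 ± 14 to 6.51 ± 1.92 CPM (-3.29, SE 0.30, edgeR adjusted p = 5.8e-05), and the quinone reductase gene Nqo1 fell by 2.92 on the log2 scale (SE 0.41). The glutathione transferase Gsta4 fell by 1.47 on the log2 scale and Pgd of the pentose phosphate pathway by 1.09. The member that rose was Slc7a11, a cystine transporter that ATF4 also regulates (3.98, SE 1.02, chosen after its values were seen). It lost the threshold without untreated replicate 1 or BPA replicate 1 or 3 (edgeR adjusted p up to 0.136).

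Mitotic genes fell in 11 of 25 cases and rose in 0 (16 and 0 when adjusted over the list alone; median -0.84, camera adjusted p = 8.4e-07, and adjusted p = 0.163 with an estimated correlation). The kinase gene Aurka fell from 255 ± 24.3 to 86.3 ± 10 CPM (-1.56, SE 0.16, edgeR adjusted p = 0.00015). The checkpoint gene Bub1b fell by 1.15 on the log2 scale and the cyclin gene Ccnb2 by 1.28. DNA replication genes had 2 of 30 members higher and 4 lower (2 and 9 when adjusted over the list alone; camera adjusted p = 0.151, and 0.0496 after the GC and length correction, range over the alternatives 0.0496 to 0.279). The lower ones were Cdc45 (-0.87), Rpa2 (-0.72), E2f1 (-0.94) and Rrm1 (-0.73). E2f1 lost the threshold without untreated replicate 2 (edgeR adjusted p = 0.0537) and Rrm1 without any untreated replicate or BPA replicate 1 (up to 0.162). The number lower was 2 without untreated replicate 2, 10 without BPA replicate 2 and 8 after the GC and length correction, and scaling by library size gave 3 higher and 3 lower. The higher members, chosen after their values were seen, were Chek1 (2.67) and Pole (0.59), which lost the threshold without any library other than BPA replicate 2 (edgeR adjusted p up to 0.15 and 0.185).

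Cholesterol synthesis genes were lower for 9 of 25 members and higher for 1 (11 and 1 when adjusted over the list alone; median -0.72, camera adjusted p = 1.5e-05, and adjusted p = 0.163 with an estimated correlation). The squalene synthase gene Fdft1 fell from 353 ± 8.3 to 181 ± 24.5 CPM (-0.97, SE 0.15, edgeR adjusted p = 0.0018). Mvk fell by 2.08 and lost the threshold without untreated replicate 1 (edgeR adjusted p = 0.0556). The number of lower members was 2 without untreated replicate 1, 6 without untreated replicate 2 or 3, 4 without BPA replicate 1 and 6 without BPA replicate 3. Without each library in turn the list kept its call with the preset correlation (camera adjusted p 1.9e-05 to 0.00014).

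Nuclear genes of the respiratory chain fell in 12 of 38 cases and rose in 0 (19 and 0 when adjusted over the list alone; median -0.43, camera adjusted p = 1.0e-05, and adjusted p = 0.409 with an estimated correlation). The subunit genes Cox7a2 and Cox7c fell by 1.56 and 1.61 on the log2 scale (SE 0.20 and 0.25). The number of lower members was 2, 3 and 7 without untreated replicates 1, 2 and 3, and 2, 20 and 5 without BPA replicates 1, 2 and 3. In these fits the list kept its call with the preset correlation (camera adjusted p 1.3e-05 to 0.00025). Of 13 genes of the mitochondrial genome 2 were lower and 0 higher (5 and 0 when adjusted over the list alone; median -0.42, camera adjusted p = 0.011, and adjusted p = 0.589 with an estimated correlation). They were mt-Nd3, at -1.92 (SE 0.25), and mt-Co3, at -0.75, whose counts lay within 5% of those of a nuclear copy on chromosome 1 in every library and whose value is therefore uncertain. mt-Co3 lost the threshold without untreated replicate 1 or 2 or BPA replicate 3 (edgeR adjusted p up to 0.114). The list lost its call without BPA replicate 3 (camera adjusted p = 0.0594) and after the GC and length correction (0.14, median -0.11; range over the alternatives 0.00019 to 0.14), the number lower was 1 without untreated replicate 1 or 2 or BPA replicate 3 and 5 and 6 without BPA replicates 1 and 2, 5 in limma-voom, with no low-count filter or with a replicate block, and scaling by library size alone gave 2 members higher and 1 lower. Glycolysis and hypoxia genes were lower for 8 of 28 and higher for 1 (10 and 2 when adjusted over the list alone; median -0.38, camera adjusted p = 0.042, and adjusted p = 0.589 with an estimated correlation). The lactate dehydrogenase gene Ldha fell from 489 ± 30.4 to 178 ± 14.6 CPM (-1.46, SE 0.14), and the enolase gene Eno1 by 0.98 on the log2 scale. Vegfa, chosen after its values were seen, rose by 1.54 (SE 0.31). That list lost its call without untreated replicate 2 or 3 or BPA replicate 1 or 3 (camera adjusted p = 0.0897, 0.0767, 0.105 and 0.0654; range over the alternatives 0.00497 to 0.105), and the number lower was 4, 2 and 4 without untreated replicate 1, untreated replicate 2 and BPA replicate 1.

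Targets of p53 were higher for 3 of 25 members and lower for 2 (6 and 2 when adjusted over the list alone; median 0.46, camera adjusted p = 0.042, and adjusted p = 0.315 with an estimated correlation). Bbc3, which encodes the cell death activator PUMA, rose from 21.2 ± 2.63 to 84.8 ± 16.6 CPM (2.00, SE 0.23, edgeR adjusted p = 0.00028). Mdm2 rose by 1.93 and lost the threshold without untreated replicate 1 (edgeR adjusted p = 0.069), and Plk2, chosen after its values were seen, rose by 0.69 and lost it without any library other than BPA replicate 2 (up to 0.192). Rps27l and Tigar fell by 0.85 and 0.95, the former losing the threshold without untreated replicate 1 or 2 or BPA replicate 1, the latter without any library other than BPA replicate 2 (edgeR adjusted p up to 0.109 and 0.117). The list lost its call without untreated replicate 3 or BPA replicate 3 (camera adjusted p = 0.056 and 0.0594; range over the alternatives 0.012 to 0.0594). The number higher was 1 without untreated replicate 1, 7 without BPA replicate 2 or after the GC and length correction, and 5 with scaling by library size or no low-count filter. Among 24 BCL2 family and caspase genes 2 were higher and 2 lower, the same when adjusted over the list alone (camera adjusted p = 0.511), and the number lower was 4 without BPA replicate 2 or after the GC and length correction and 1 with scaling by library size. Hrk, another cell death activator, had 0 counts in untreated and 282 in BPA libraries, at least 70.2-fold higher, and Bok fell by 1.85 on the log2 scale. The others were Casp2 at 0.65 and Cycs at -0.99, which lost the threshold without any untreated replicate or BPA replicate 3, and Casp2 also without BPA replicate 1 (edgeR adjusted p up to 0.16 and 0.139).

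Immediate early and ERK feedback genes were higher for 7 of 23 and lower for 3 (11 and 3 when adjusted over the list alone; median 0.65, camera adjusted p = 0.018, and adjusted p = 0.683 with an estimated correlation). Ier2 rose by 1.39 (SE 0.16) and the ERK phosphatase gene Dusp6 by 1.15 (SE 0.14). Ier3 fell by 1.16 (SE 0.19), as did Etv4 and Dusp5, chosen after their values were seen, by 0.73 and 0.75. Etv4 and Dusp5 lost the threshold without untreated replicate 1 or 2 or BPA replicate 1 or 3, and Dusp5 also without untreated replicate 3 (edgeR adjusted p up to 0.128 and 0.137). The list lost its call without untreated replicate 3 or BPA replicate 2 (camera adjusted p = 0.056 and 0.171; range over the alternatives 0.000276 to 0.171). The number higher was 2, 3 and 4 without untreated replicates 1, 2 and 3 and 4 without BPA replicate 1, but 10 with scaling by library size and 12 after the GC and length correction.

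The largest changes included genes nearly silent in 1 group, and 12 of the 24 genes with the largest folds had 3 or fewer counts there. The secreted stanniocalcin gene Stc2 (ENSMUSG00000020303, chromosome 11, 31357307 to 31370074) had 1 count in untreated and 1758 in BPA libraries, a ratio of 1312 with a 95% exact counting interval of 235 to 51863. The peptide hormone gene Adm2 rose from 0.0731 ± 0.127 to 37.9 ± 6.79 CPM. Cox6a2 had 1 count against 316. Inhbe had 0 against 168 and was at least 41.8-fold higher, and it lost the threshold without untreated replicate 1 or BPA replicate 3 (edgeR adjusted p up to 0.0988). Among genes that fell, the interferon-induced gene Ifitm1 went from 21.0 ± 11.8 to 1.16 ± 0.375 CPM and the keratin gene Krt24 from 11.6 ± 1.6 to 1.08 ± 0.338 CPM. Krt19, a keratin of simple epithelia, fell from 60.4 ± 7.89 to 4.95 ± 0.884 CPM (-3.61, SE 0.28, edgeR adjusted p = 1.3e-05).

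Genes of cell adhesion had 1 of 27 members higher and 4 lower (2 and 6 when adjusted over the list alone; camera adjusted p = 0.0663, range over the alternatives 0.0225 to 0.171), and 6 higher and 6 lower without BPA replicate 2. The list passed without BPA replicate 1 (camera adjusted p = 0.0346), with scaling by library size (0.0471), with no low-count filter (0.0225) and with at least 1 CPM in 3 samples (0.0426). It also passed by fry (fry adjusted p = 0.00353) but not with an estimated correlation (camera adjusted p = 0.327). The lower members were Krt19, the surface protein gene Cd9 and the cadherin gene Cdh3, both at -1.13, and Krt8 (-0.87), which lost the threshold without any untreated replicate or BPA replicate 3 (edgeR adjusted p up to 0.121). The higher one was Ctnnb1, which encodes beta-catenin and was chosen after its values were seen (0.63; lost without untreated replicate 1 or 2 or BPA replicate 1 or 3, edgeR adjusted p up to 0.167). Receptors and targets of estrogen had 1 of 14 higher and 0 lower (2 and 0 over the list alone; camera adjusted p = 0.887), and 2 higher and 3 lower without BPA replicate 2, and 2 higher and 0 lower after the GC and length correction. That gene was the retinoic acid receptor gene Rara, at 1.02, which lost the threshold without untreated replicate 1 or 2 (edgeR adjusted p up to 0.0775). Esr1 and Esr2, the estrogen receptors, stood at 0.497 ± 0.368 and 0.406 ± 0.451 CPM and at 0.909 ± 0.987 and 0.638 ± 0.528 CPM in untreated and BPA cultures, levels at which only large changes were detectable. Of 11 aryl hydrocarbon receptor and xenobiotic genes 0 passed in edgeR, also over the list alone (camera adjusted p = 0.504), although Por passed as higher after the GC and length correction (0.36, edgeR adjusted p = 0.0326). The KEGG term for xenobiotic metabolism by cytochrome P450, tested after the results were seen, had 5 of 25 genes lower and 1 higher (median -0.69). Its camera adjusted p was 0.0492, but 0.834 with an estimated correlation and 0.145 after the GC and length correction. Cyp1a1 was at 0.274 ± 0.474 and 0.547 ± 0.48 CPM. Among 26 DNA methylation and histone modifying enzymes 1 was higher and 2 lower, the same over the list alone (camera adjusted p = 0.331), and 5 were higher and 4 lower without BPA replicate 2. Scaling by library size gave 3 higher and 2 lower, and the GC and length correction 4 higher and 3 lower. The histone demethylase gene Kdm5b rose by 1.02 (SE 0.16), and Dnmt3l and Uhrf1 fell by 1.61 and 0.61 on the log2 scale. Dnmt3l and Uhrf1 lost the threshold without untreated replicate 1 or 2 or BPA replicate 3, and Uhrf1 also without BPA replicate 1 (edgeR adjusted p up to 0.0611 and 0.0998). The methyltransferase genes Dnmt1, Dnmt3a and Dnmt3b were at 0.18, -0.14 and -0.06 (edgeR adjusted p = 0.47, 0.66 and 0.88). Of 23 imprinted genes 2 were higher and 3 lower, the same over the list alone (camera adjusted p = 0.511), which were Igf2r (1.25), Grb10 (1.46), Nnat (-1.32), Mest (-1.29) and H19 (-0.52, chosen after its values were seen). Grb10 lost the threshold without untreated replicate 1 or 2 or BPA replicate 1, Mest without untreated replicate 1 or 3 or BPA replicate 1 or 3, and H19 without any library other than BPA replicate 2 (edgeR adjusted p up to 0.0786, 0.0887 and 0.185). Scaling by library size, or the GC and length correction, gave 3 higher and 3 lower imprinted genes. Gper1, Esrrg and Cyp1b1 had too few counts to be tested. Gper1 had 0, 34 and 0 counts in untreated and 0, 11 and 10 in BPA replicates 1 to 3, Esrrg 17, 0 and 1 against 0, 0 and 0, and Cyp1b1 0, 1 and 7 against 29, 12 and 28.

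Markers of other testicular and culture cell types did not pass the camera test. Of 19 fibroblast markers 0 were higher and 1 lower (0 and 0 over the list alone; median -0.16, camera adjusted p = 0.146, and 0.0486 without BPA replicate 2, range over the alternatives 0.0486 to 0.461). The number lower was 4 without BPA replicate 2, 3 with no low-count filter or a replicate block, and 2 in limma-voom and after the GC and length correction. The lower marker was Loxl1, at -1.30, which lost the threshold without any library other than BPA replicate 2 (edgeR adjusted p up to 0.188). Of 7 Sertoli cell markers Clu rose by 1.34, Sox9 rose from 8.64 ± 0.55 to 24.5 ± 5.01 CPM and 0 were lower, the same over the list alone (camera adjusted p = 0.119; 0.0374 with at least 1 CPM in 3 samples and 0.0496 after the GC and length correction, range over the alternatives 0.0374 to 0.74), and Sox9 lost the threshold without untreated replicate 1 (edgeR adjusted p = 0.0594). The peritubular and Leydig lists each had 1 lower member, of 7 and 3 tested, also over the list alone (camera adjusted p = 0.504 and 0.887). These were Tagln and Scarb1, and both lost the threshold without untreated replicate 1 or 2 or BPA replicate 1 or 3 (edgeR adjusted p up to 0.196 and 0.0773). Of 4 macrophage, 5 endothelial and 3 spermatid markers 0 passed in edgeR over all genes, and over the list alone 1 endothelial marker was lower, Egfl7 (-0.90; camera adjusted p = 0.231, 0.231 and 0.504). The macrophage markers Cd68 and Lyz2 passed as lower in edgeR, Cd68 without BPA replicate 2 (-0.82, adjusted p = 0.0151) and Lyz2 without BPA replicate 3 (-3.99, adjusted p = 0.0262). The macrophage list passed as lower without BPA replicate 3 (camera adjusted p = 0.0352) and with no low-count filter (0.0249), and the endothelial list without untreated replicate 2 (0.0461), with ranges over the alternatives of 0.0249 to 0.363 and 0.0461 to 0.285. Egfl7 passed over all genes in edgeR without BPA replicate 2 (adjusted p = 0.0239), with no low-count filter (0.0308) and after the GC and length correction (0.0489), in DESeq2 (0.0144) and in limma-voom (0.0406).

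In the remaining lists, the higher and lower members were 2 and 1 of 27 autophagy and lysosome genes, 1 and 3 of 24 fatty acid genes, 0 and 2 of 18 heat shock genes, 0 and 1 of 10 metal response genes and 1 and 0 of 19 interferon and inflammation genes. Each of these counts was the same when adjusted over the list alone, and the camera adjusted p was 0.887, 0.935, 0.254, 0.231 and 0.935. Without BPA replicate 2 the higher and lower members were 5 and 4, 2 and 5, 1 and 4, 1 and 3, and 1 and 1, and after the GC and length correction 4 and 3, 2 and 5, 0 and 1, 0 and 0, and 3 and 0. The heat shock gene Hspa8 fell from 2385 ± 255 to 1062 ± 240 CPM (-1.17, SE 0.17, edgeR adjusted p = 0.0011). The others were Lamp1 (0.64), Ctsl (0.57) and Tfeb (-0.93), Fabp3 (1.88), Hadhb (-0.90), Acadvl (-0.73) and Scd2 (-0.98), Dnajb1 (-0.72), Mt1 (-0.81) and Icam1 (0.81). Lamp1 and Icam1 lost the threshold without untreated replicate 1 or 2, Tfeb also without BPA replicate 1, Hadhb without untreated replicate 3 and Dnajb1 without any untreated replicate (edgeR adjusted p up to 0.061, 0.0715, 0.0715, 0.0577 and 0.0882). Fabp3 lost it without untreated replicate 1 or 3 or BPA replicate 1 or 3, and Ctsl, Acadvl, Scd2 and Mt1 without any library other than BPA replicate 2 (edgeR adjusted p up to 0.145, 0.179, 0.117, 0.166 and 0.173). Cytosolic ribosomal protein genes had 3 of 32 higher and 4 lower (5 and 8 over the list alone; camera adjusted p = 0.246), and 7 and 13 without BPA replicate 2. The balance turned to 5 higher and 4 lower with scaling by library size and to 8 higher and 3 lower after the GC and length correction (median -0.14 before and 0.03 after). The higher ones, chosen after their values were seen, were Rps24 (0.61), Rps4x (0.67) and Rps6 (0.39), and the lower ones included Rplp1 (-0.77), Rps3 (-0.51) and Rpl19 (-0.43). Of these 6, all but Rplp1 lost the threshold without untreated replicate 1 or 2 or BPA replicate 1 (edgeR adjusted p up to 0.194). Without BPA replicate 3 it was lost by Rps24, Rps6, Rps3 and Rpl19, and without untreated replicate 3 by Rps24. Rplp1 and Rpl19 were at -0.051 and 0.037 after the GC and length correction. The median, the mean and the camera direction differed in sign for 6 lists, those of differentiation, Leydig cells, cell death, autophagy, fatty acids and estrogen.

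Genes were tested with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and the lists with limma's camera, where 9 of 33 passed, 0 with an estimated correlation (5 at an unadjusted p under 0.05) and 7 by fry. Fry did not call the glycolysis, mitochondrial genome and immediate early lists (fry adjusted p = 0.0678, 0.126 and 0.126). It called the cell adhesion list (fry adjusted p = 0.00353), which camera did not call. The number of genes past the threshold was 444, 527 and 833 without untreated replicates 1, 2 and 3, and 583, 2807 and 710 without BPA replicates 1, 2 and 3. Of the 1415 genes, 30.2%, 35.8% and 55.9% kept their call without untreated replicates 1, 2 and 3. Without BPA replicates 1, 2 and 3 these shares were 40%, 96.7% and 48.6%. Among the genes named here, limma-voom ended the calls of Dppa3, Tex11, Mei4, Prdm9, Slc7a11, Chek1 and Tagln (adjusted p 0.0501 to 0.155), and a replicate block in edgeR those of Mei4, Prdm9 and Chek1 (0.0566 to 0.134). Scaling by library size in edgeR ended those of Id4, Cycs, Loxl1, Tagln, mt-Co3, Rrm1 and Scd2 (adjusted p 0.0517 to 0.098), and no low-count filter those of Rpl19 and Rps6 (0.0515 and 0.0753). The GC and length correction, chosen after the results were seen, ended in edgeR those of Id4, Crabp1, Casp2, Pole, Loxl1, Rplp1, Rpl19, mt-Co3, Krt8, Dnajb1 and Mt1 (adjusted p 0.0531 to 0.833). Pou5f1, Uchl1, Fdft1, Cd9, Cox6a2, Acadvl, Fabp3, Mest and Nanos2 share 10.3% to 49.0% of their exon length with another annotated gene, whose reads cannot be told from theirs without strand, and their values are uncertain to that extent. BPA replicate 2 stood apart in GC content: across genes, which are not independent replicates, the Spearman correlation of GC content with the change against the untreated mean was 0.18 in it, and -0.36 and -0.41 in BPA replicates 1 and 3.

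**Figure D3:**
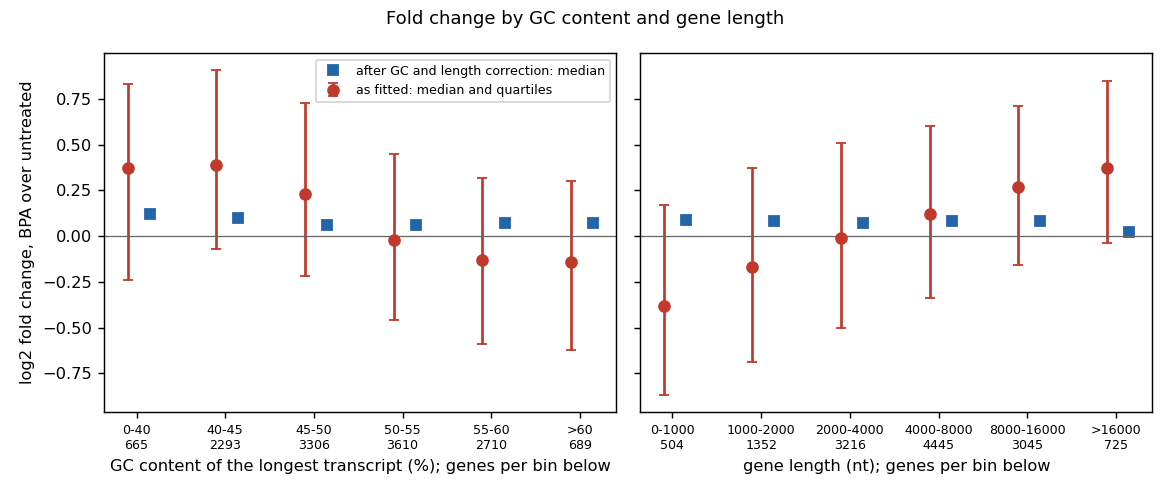
Median log2 fold change (circles, with quartiles as bars) of the tested genes by GC content (left) and gene length (right), and the median after correction of each library for both (squares). The median went from -0.38 in genes of up to 1000 nt to 0.37 in genes over 16000 nt, and lay between 0.02 and 0.12 in every bin after the correction.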

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

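The GC and length correction was chosen after the results were seen. Each library matters for the counts: leaving out 1 library at a time gave 444 to 2807 genes past the threshold, 162 to 1207 higher, 282 to 1600 lower, 376 to 1263 changed at least 2-fold, and 6 to 10 lists. BPA replicate 2 was the library whose removal raised the total, and untreated replicate 1 the one whose removal gave the lowest. The cause was not tested, beyond the smaller number of samples. DESeq2 gave 2166 genes, 938 of them higher, and on simulated counts it also made more false calls. No low-count filter gave 927 higher genes among more genes tested. The GC and length correction gave 2087 genes, 1023 higher and 1064 lower, and an FDR of 0.01 gave 477 genes, 155 higher and 322 lower. With an estimated correlation 0 lists passed, against 5 at an unadjusted p under 0.05. Correlation between genes is not the only difference between these forms of camera. The p53 list had an estimated correlation of -0.018, below the preset 0.01. Its unadjusted camera p was still 0.0112 with the preset and 0.0477 with the estimate. The loss of the calls therefore does not measure correlation alone. Rpl19 turned from -0.43 to 0.037 after the GC and length correction, in which it did not pass. The other reasons for these differences were not tested.

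Over the other scalings, filters and tools, the replicate block, the GC and length correction and the left-out libraries, named genes kept their direction and side of the threshold in 1656 cases, lost the threshold in 268, gained it in 16 and reversed in 1 (Rpl19), and lists kept theirs in 414, lost it in 10 and gained it in 12. In 40 more cases a named gene changed direction without passing in either fit or had no DESeq2 adjusted p, and in 24 a list changed direction without passing in either. These tallies leave out the FDR of 0.01, the estimated correlation, with which the 9 lists lost their calls, and fry, which called 7 lists. They also leave out the genes chosen after their values were seen. Those kept their direction and side of the threshold in 401 cases and lost the threshold in 75. In 4 more they changed direction without passing in either fit or had no DESeq2 adjusted p. No gene called in the 1415 was called in the opposite direction by any of these alternatives. The replicate numbers gave no clear sign of pairing: the correlations of deviations between same-numbered samples were -0.02, 0.06 and 0.07. Untreated replicates 2 and 3 correlated best with their own numbers, and untreated replicate 1 did not. With 3 samples per group these correlations cannot settle whether the samples were paired. The replicate block gave 1706 genes, 721 higher and 985 lower, 845 changed at least 2-fold, and 9 lists. The camera test was not run on DESeq2's fit. At 13453280 to 22286517 counts per library, changes of genes under 1 CPM were mostly not detectable.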

Other observations

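The tests of KEGG terms and of single aminoacyl-tRNA synthetase and proteasome genes, the split of the stress list into 2 sets, the GC profile of single libraries, the fibroblast test, the single fibroblast markers and the GC and length correction were chosen after the results were seen. Genes that charge transfer RNAs with amino acids were higher in 11 of 43 cases and lower in 1 (camera adjusted p = 0.0538 over 269 KEGG terms, range over the alternatives 0.00384 to 0.198, and adjusted p = 0.834 with an estimated correlation). Gars, Sars, Mars and Nars, cytosolic synthetases for glycine, serine, methionine and asparagine, rose by 1.85, 1.52, 1.56 and 2.17 on the log2 scale (SE 0.15, 0.14, 0.16 and 0.22), each without overlap of the groups. Qars, the glutaminyl-tRNA synthetase gene, fell by 0.68 (SE 0.14). It lost the threshold without untreated replicate 1 or 2 or BPA replicate 1 (edgeR adjusted p up to 0.0873). Wars, the tryptophanyl-tRNA synthetase gene, was at 110 ± 2.97 and 102 ± 8.75 CPM (edgeR adjusted p = 0.73).

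Of the 269 KEGG terms 9 passed with the preset correlation, all lower under BPA, and with an estimated correlation their camera adjusted p was 0.834 to 0.999. They were Parkinson's disease, oxidative phosphorylation, proteasome, ribosome, Huntington's disease, Alzheimer's disease, glutathione metabolism, non-alcoholic fatty liver disease and xenobiotic metabolism by cytochrome P450. After the GC and length correction only the first 3 kept their calls (camera adjusted p = 0.0043, 0.0086 and 0.0126). The others were at 0.0778 to 0.453. The neurodegenerative and fatty liver disease terms hold many of the respiratory chain genes of oxidative phosphorylation. The 9 terms, and the 3 that kept their calls, are therefore not independent results. Proteasome genes fell in 13 of 40 cases and rose in 0 (camera adjusted p = 0.0012, and adjusted p = 0.834 with an estimated correlation). The immunoproteasome subunit gene Psmb10 fell from 162 ± 5.44 to 52.0 ± 10.2 CPM and Psmb3 from 655 ± 64.2 to 302 ± 15.2 CPM. Glutathione metabolism had 9 of 41 genes lower and 1 higher, and the ribosome term, which includes mitochondrial ribosomal proteins, 24 of 126 lower and 6 higher. After the GC and length correction neither of these passed (camera adjusted p = 0.0778 and 0.453), and the ribosome term had 17 genes lower and 19 higher. The number of lower proteasome genes was 5 without untreated replicate 1 and 19 without BPA replicate 2. Lower ribosome genes numbered 4, 6 and 15 without untreated replicates 1, 2 and 3, and 7, 46 and 9 without BPA replicates 1, 2 and 3. For glutathione metabolism these numbers were 3, 5 and 4, and 6, 12 and 6.

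Within the stress list, 15 of 16 ATF4 targets rose (median 2.96), as did 1 of 13 chaperone, folding and degradation genes (median 0.03), a difference of medians of 2.93. These sets were drawn up after the values were seen, so the difference describes the list and does not test the split. They leave out 5 of the 34 members tested, among them Atf4 (3.81) and Herpud1 (3.70), a gene of endoplasmic reticulum degradation, which both rose. The 1 of 13 that rose was Sel1l (0.88), which lost the threshold without any library other than BPA replicate 2 (edgeR adjusted p up to 0.112) and after the GC and length correction (0.108). Sel1l and Edem1 (-0.34) of that set are, like Herpud1, genes of endoplasmic reticulum degradation. The sets therefore do not divide the list cleanly by function. The tables argue against GC content and gene length as the source, since the median of the targets was 3.04 after the correction. The fibroblast median was -0.16 over the 19 markers tested, in a test chosen after the results were seen. That value goes against more fibroblasts in the BPA cultures. It does not show which cells in the cultures raised the ATF4 targets. Of the most abundant markers, Fn1 was at 206 ± 14.8 and 271 ± 109 CPM, Sparc at 105 ± 25.7 and 85.3 ± 16.2 CPM and Timp2 at 82.1 ± 15.6 and 76.6 ± 18.9 CPM in untreated and BPA cultures. Whether an ATF4 response was engaged apart from the chaperone response stays open. What acts upstream of ATF4 was not tested.

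Longer and more AT-rich genes tended to be higher under BPA, with a Spearman correlation of the fold change of -0.25 with GC content and 0.21 with length. This trend is argued against as the cause of most calls, because 86.4% of the 1415 genes kept their direction and the threshold after the correction. The corrected fit made more calls, 2087 with 1023 higher and 1064 lower, which made the threshold easier to keep. The GC part of the trend may come from single libraries, since the correlation was 0.18 in BPA replicate 2 and -0.36 and -0.41 in the others. The length part had the same sign in all 3 BPA libraries (0.17, 0.13 and 0.19), and its source was not tested.

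Of 38 nuclear genes of the respiratory chain 12 were lower under BPA, and 2 without untreated replicate 1 or BPA replicate 1. The list did not pass with an estimated correlation (camera adjusted p = 0.409). Against 1000 random lists matched on length and GC content, the list median of -0.43 lay at percentile 0.1 (matched median -0.02), and it was -0.30 after the correction. The matched lists drew their genes singly, while the members of this list had an estimated correlation of 0.148. The spread of the matched medians may therefore be too narrow, and the percentile cannot decide the question. Length and GC content may account for a part of the lower median, and whether they account for the whole of it stays open. A lower expression of the respiratory chain under BPA remains a hypothesis.

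The 6 samples can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In 1 of the 10, the real split, 1415 genes passed, 580 higher, 835 lower and 745 at least 2-fold, against at most 0 in each of the other 9 with edgeR, where 66 to 1328 genes had an unadjusted p under 0.05 (3362 in the real split). The real split gave 9 lists and the highest of the others 4. Each of the other 9 splits mixes untreated and BPA samples in both groups. Any difference between the treatments then widens the spread within groups, so their counts of 0 do not measure chance.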
